A study of Homo sapiens with 12 samples.

How the data were processed

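The deposited table gave 1 intensity per probe set and array on a linear scale for 12 Affymetrix expression arrays, hybridised with biotin-labelled RNA and read in a single colour. The algorithm that made the intensities, any scaling of the arrays and any detection calls were not given in the sources used here. The table held 54675 probe sets, of which 62 were controls. The probe-to-gene table gave exactly 1 symbol for 41097 of all probe sets, several symbols for 1801 and none for 11777. Symbols were matched by gene identifier to a table of RefSeq genes on the human assembly GRCh38.p14, which placed 14364 of the genes tested on chromosomes 1 to 22 and X.

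The following were chosen before the data were examined: the groups, the tests, the thresholds, the gene lists, the rule for naming genes and most of the alternatives. Means with 2% trimmed from each end differed by a factor of 1.34 between the highest and the lowest array, beyond the tolerance of 5%, so all arrays were scaled to a common trimmed mean. Values below the 20th percentile of the scaled table (11.03) were set to that floor and log2 was taken. Probe sets at or above the 50th percentile (27.7) in at least 3 of the 12 arrays were kept, which left 31699 probe sets and 14410 genes. Each gene was represented by the probe set with the highest mean log2 value among those with exactly 1 symbol. The means and SD given for genes are of the scaled intensities before the floor, and the fold changes are of the log2 values after it. A fold change is given as a lower limit where 2 or 3 arrays of a group lay at the floor, and where 1 array did, its size is understated.

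All 12 arrays entered 1 linear model with 1 coefficient per group, fitted with limma (lmFit, then eBayes with trend and robust) and read out in 6 comparisons. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 31699 probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Adjusted p-values for genes are from this test. The 3 arrays of each group were taken as independent, since the labels call them biological replicates. Whether they are separate cultures, clones or, for caMCF, tumours is not stated. The p-values therefore measure the spread between the arrays of a group, and not between separate transformations or clones. Beside each comparison of 3 arrays with 3 it holds that 10.0% of genes with no difference would by chance have all arrays of one group beyond all arrays of the other.

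The 20 gene lists were written from general knowledge of the field. They held mesenchymal, epithelial junction, basal epithelial, luminal epithelial, estrogen-response, estrogen metabolism, cell cycle, p53 target, interferon-stimulated, inflammatory, protease, hypoxia and glycolysis, cholesterol biosynthesis, oxidative stress and ribosomal protein genes. The remaining 5 lists held genes typical of fibroblasts, leukocytes, endothelial cells and adipocytes, and the genes of 9p21. Some genes stand in more than 1 list, such as PERP (p53 target and epithelial junction) and SFN (p53 target and basal epithelial), so the lists are not separate results. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01 against all genes tested, with Benjamini-Hochberg adjustment over 120 tests. The genes of each chromosome were tested as sets in the same way. Members that rose or fell were counted with the adjustment over all probe sets and with the adjustment over the list alone. List members without a probe set of exactly 1 symbol, or below the filter, were not tested.

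Genes were named by a fixed rule in 4 comparisons: trMCF with MCF-10F, bcMCF with trMCF, caMCF with bcMCF, and caMCF with MCF-10F. Named were the 10 largest rises and 10 largest falls with an adjusted p under 0.05, no overlap between the arrays of the groups and at least 2 of 3 arrays above the floor in both groups. Up to 5 called genes with one group wholly at the floor were added. From each list described, up to 2 rises and 2 falls were taken, and CDH1, VIM, FN1, ESR1, ESR2, KRT5, KRT14, KRT18 and MKI67 were always followed. The text gives the genes of these groups that matter most. Any gene named outside this rule is said to have been chosen after its values were seen.

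The alternatives were no filter, a stricter filter at the 70th percentile, a floor at the 5th percentile, quantile normalization, median centring, eBayes without trend and not robust, a fit of only the 2 groups compared, a block for the replicate number, a treat test against a 1.5-fold change, and leaving out each array in turn. For the sets they were an estimated inter-gene correlation, fry, camera on ranks and the mean of all probe sets of a gene. Array quality weights, and leaving out both arrays that stood apart, were added after the data had been seen, as was the ERK gene list without CCND1. The method was tested on simulated data for trMCF against MCF-10F. With true changes of 0.5, 1 and 2 on the log2 scale it called 3 of 68, 31 of 66 and 58 of 66 changed probe sets, with 2 false calls, so most simulated changes of 0.5 were missed. Far fewer probe sets were changed there than were called in any real comparison, so these shares may not hold for the real data. By limma the method called 0 probe sets where nothing was changed. Among 20 simulated lists, the 1 that had been shifted was called and 0 of the 19 unshifted ones were. The simulated genes varied independently of each other. This test therefore cannot show how often real lists, whose genes are correlated, would be called in error.

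The control probe sets were left out of all counts and lists. Of the 52 controls tested apart by limma, in the comparisons with MCF-10F only, 1 was called, a spiked-in Phe control that was lower in bcMCF and caMCF than in MCF-10F (log2 change -1.05, adjusted p = 0.038 in both). The equal change would arise if both groups lay at the floor, and its size may then be understated. The other Phe probe sets were not called and were higher in both groups, by up to 0.98 (bcMCF, adjusted p = 0.08). The DNA arrays of the study were not used. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.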

Results

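Expression was measured on 12 arrays from 4 groups of human breast epithelial cells, with 3 arrays per group. MCF-10F is a spontaneously immortal, non-tumorigenic epithelial line that is described as lacking the estrogen receptor and was grown without estradiol. The trMCF cells are MCF-10F cells transformed by 70 nM 17-beta-estradiol. The bcMCF cells are a clone of trMCF-derived cells that had crossed the membrane of a Boyden chamber, which selects for invasion. The caMCF cells are lines grown out of tumours that such invasive cells formed in immunodeficient mice. Each array gave 1 intensity per probe set. Between arrays the 2% trimmed mean ran from 44.2 to 59.3 before scaling, and 15.7% to 22.2% of the scaled values lay at the floor of 11.03. The number of arrays, 3 per group, limited the precision of every value below.

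The groups fell into 2 pairs. The first principal component held 46.3% of the variance and placed MCF-10F at -69.2 to -57.6, trMCF at -46.8 to -41.8, bcMCF at 26.8 to 61.8 and caMCF at 58.6 to 62.1. The second held 14.7%, and bcMCF replicate 3 stood apart on it at 82.7, with all other arrays between -43.4 and 22.6. This array also had the lowest trimmed mean, 44.2. The mean correlation between bcMCF arrays (0.904) was no higher than that between bcMCF and caMCF arrays (0.906), while it was 0.961 within caMCF and 0.827 between MCF-10F and bcMCF and 0.828 between MCF-10F and caMCF. In MCF-10F replicate 3 the ratio of 3' to 5' signal was 1.65 for GAPDH and 1.497 for ACTB, against 1.04 to 1.07 and 1.04 to 1.08 in the other 2 MCF-10F arrays, and its 28S ribosomal RNA signal was 997 against 41.6 to 592 elsewhere. The ACTB ratio was also raised in bcMCF replicates 1 and 2 (1.395 and 1.323) and in caMCF (1.478, 1.476 and 1.182), against 1.005 to 1.021 in trMCF and 0.978 in bcMCF replicate 3. The GAPDH ratio was 1.19 to 1.43 in bcMCF and caMCF and 1.13 to 1.18 in trMCF, so these signs of RNA quality differed between the same groups as the genes below. The counts of probe sets, and those list counts of 4 or more that moved by over 1.5 times, are also given without MCF-10F replicate 3 and bcMCF replicate 3, the 2 arrays that stood apart, a choice made after the data were seen. MCF-10F replicate 3 stood apart by its RNA signals and bcMCF replicate 3 on the second component. On the first component bcMCF replicate 1 lay at 26.8, against 52.9 and 61.8 for the other bcMCF arrays, and it was kept. This setting therefore does not cover every array that may be doubted.

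**Figure D1:**
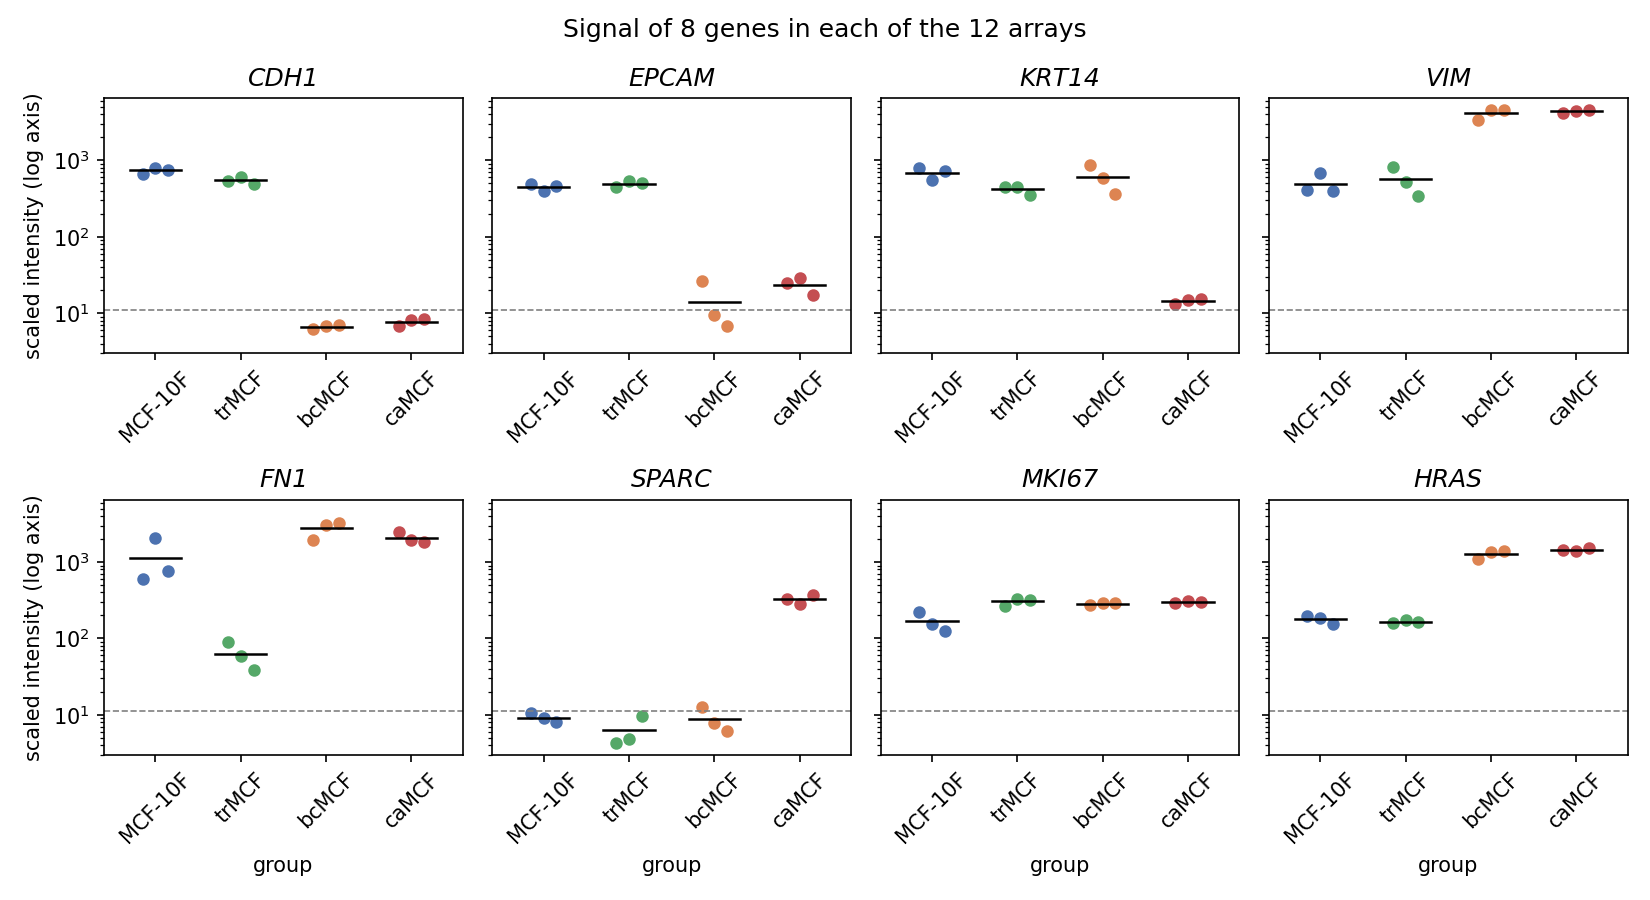
Scaled intensity of 8 genes on a log axis in MCF-10F, trMCF, bcMCF and caMCF. Each point is 1 array (n = 3 per group), the black line is the mean of the group and the dashed line is the floor of 11.03. CDH1 averaged 745 in MCF-10F and 7.70 in caMCF. EPCAM, SPARC and HRAS were chosen after their values were seen.

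The comparison of trMCF with MCF-10F asks how the cells transformed by estradiol differed from the parental cells. The largest rise was that of DCN, which encodes the matrix proteoglycan decorin, 6.59-fold from 15.4 ± 1.28 to 109.7 ± 56.2 (SD, n = 3; adjusted p = 4.94e-05). S100A7, a calcium-binding protein first found in psoriatic skin, rose 5.81-fold from 18.5 ± 14.0 to 113 ± 9.03 (SD, n = 3; adjusted p = 0.000463). FN1, which encodes the matrix protein fibronectin, fell 16.7-fold from 1140 ± 798 to 62.3 ± 25.5 (SD, n = 3; adjusted p = 0.00149), with 3 of its 6 other probe sets called lower as well. TRIM22, an interferon-induced antiviral gene, fell at least 22.96-fold from 257 ± 54.9 (SD, n = 3) to the floor (adjusted p = 7.06e-08). SRGN, which encodes the granule proteoglycan serglycin, fell 11.6-fold from 148 ± 25.3 to 12.5 ± 2.36 (SD, n = 3; adjusted p = 4.45e-07). GDF15, a stress cytokine and p53 target, fell 8.01-fold (adjusted p = 0.00055), and the matrix protease gene MMP7 fell 6.33-fold (adjusted p = 0.000552). SOX2, a stem-cell transcription factor, rose 3.92-fold (adjusted p = 0.0139), a call that was lost without MCF-10F replicate 3 (adjusted p = 0.0796), trMCF replicate 1 (adjusted p = 0.0786) or trMCF replicate 3 (adjusted p = 0.0861) and with a lower floor (adjusted p = 0.0891). CENPV, which encodes a centromere protein, rose 3.56-fold from 61.3 ± 19.4 to 211 ± 6.47 (SD, n = 3; adjusted p = 0.000114). The genes for E-cadherin, CDH1 (log2 change -0.44, adjusted p = 0.154), vimentin, VIM (0.14, adjusted p = 0.902), and the basal keratins KRT5 (-0.18, adjusted p = 0.595) and KRT14 (-0.71, adjusted p = 0.137) were not called.

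Cell cycle genes made up the clearest shift of a list in trMCF. Of 55 measured, 29 rose, 0 fell and 26 were not called (49 rose adjusted over the list alone), with a median log2 change of 0.64 (camera adjusted p = 5.9e-37; adjusted p = 0.0248 with an estimated correlation). MYBL2, a transcription factor of the cell cycle, rose 2.02-fold from 145 ± 24 to 290.6 ± 27.7 (SD, n = 3; adjusted p = 0.00247), and the replication factor MCM10 rose 1.92-fold (adjusted p = 0.0395). The proliferation marker MKI67 rose 1.88-fold from 167.8 ± 51.7 to 306.7 ± 34.0 (SD, n = 3; adjusted p = 0.00947), with 1 of its 3 other probe sets called higher as well. That call for MKI67 was lost without MCF-10F replicate 3 (adjusted p = 0.0576), without trMCF replicate 3 (adjusted p = 0.0514) and without a filter (adjusted p = 0.0502). Without the 2 arrays that stood apart, 15 cell cycle genes rose.

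Basal epithelial genes moved down in trMCF: of 29 measured, 6 fell, 1 rose and 22 were not called (13 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 2.87e-05; adjusted p = 0.0651 with an estimated correlation). IVL, a precursor of the cornified envelope of keratinocytes, fell 2.20 on the log2 scale. Of 43 epithelial junction genes 1 fell and 0 rose (the same 1 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 5.09e-05; adjusted p = 0.0937 with an estimated correlation). That gene was RAB25, which directs vesicle traffic in epithelia (log2 change -0.75). Of 44 mesenchymal genes 7 fell and 2 rose (15 and 3 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00057; adjusted p = 0.259 with an estimated correlation). FN1 and the N-cadherin gene CDH2 (log2 change -1.61) fell, while DCN and LOX, which encodes a collagen cross-linking enzyme, rose (LOX 2.06-fold, adjusted p = 0.041). Without the 2 arrays that stood apart 1 mesenchymal gene rose and 5 fell. Of 35 genes of extracellular proteases and their inhibitors 8 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 1.31e-05; adjusted p = 0.177 with an estimated correlation). FAP, which encodes a fibroblast surface protease, fell 4.54-fold, and TIMP3, which encodes an inhibitor of matrix proteases, rose 2.40-fold (adjusted p = 0.0363).

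Of 25 p53 target genes 4 fell and 0 rose in trMCF (7 and 0 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 1.7e-06; adjusted p = 0.214 with an estimated correlation). TP53I3, which encodes a p53-induced oxidoreductase, fell 3.98-fold from 591 ± 108 to 148 ± 25.2 (SD, n = 3; adjusted p = 0.000489). Of 38 interferon-stimulated genes 4 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 6.92e-06; adjusted p = 0.308 with an estimated correlation). Without the 2 arrays that stood apart 2 interferon-stimulated genes fell. ISG20, an antiviral exonuclease gene, fell 3.68-fold (adjusted p = 0.000489). Of 36 inflammatory genes 1 fell and 0 rose (camera adjusted p = 0.368), and this list was called lower without MCF-10F replicate 1 (adjusted p = 7.88e-07). The fall was that of CD44, a hyaluronan receptor gene (1.64-fold, adjusted p = 0.00831).

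Among metallothionein and oxidative stress genes, 2 of 29 rose and 1 fell in trMCF (4 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0159; adjusted p = 0.0939 with an estimated correlation). The reductase gene AKR1B10 rose 2.20-fold (adjusted p = 0.0184), and the call of the list was lost without MCF-10F replicate 1 (adjusted p = 0.0832) and without a filter (adjusted p = 0.0647). Without the 2 arrays that stood apart 1 gene of this list rose and 0 fell. Of 41 ribosomal protein genes 0 were called by limma and 9 were higher and 1 lower at an unadjusted p under 0.05, with a median of 0.097 (camera adjusted p = 0.00219; adjusted p = 0.487 with an estimated correlation; fry adjusted p = 0.115). The ribosomal call was lost without MCF-10F replicate 2 (adjusted p = 0.0671), without trMCF replicate 2 (adjusted p = 0.0645) and with the mean of all probe sets of a gene (adjusted p = 0.108).

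In total, 885 of 31699 probe sets were called between trMCF and MCF-10F by limma, 328 higher and 557 lower in trMCF, of which 428 differed at least 2-fold. Of the 14410 genes, each read by its representative probe set, 482 were called. The count of probe sets was 489 without the 2 arrays that stood apart. With single arrays left out it was 374 without MCF-10F replicate 2, 236 without MCF-10F replicate 3, 352 without trMCF replicate 1, 398 without trMCF replicate 2 and 318 without trMCF replicate 3. The balance of directions was not stable, with 550 higher and 555 lower without MCF-10F replicate 1, 68 and 284 without trMCF replicate 1, and 1644 and 1485 with array quality weights.

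**Figure D2:**
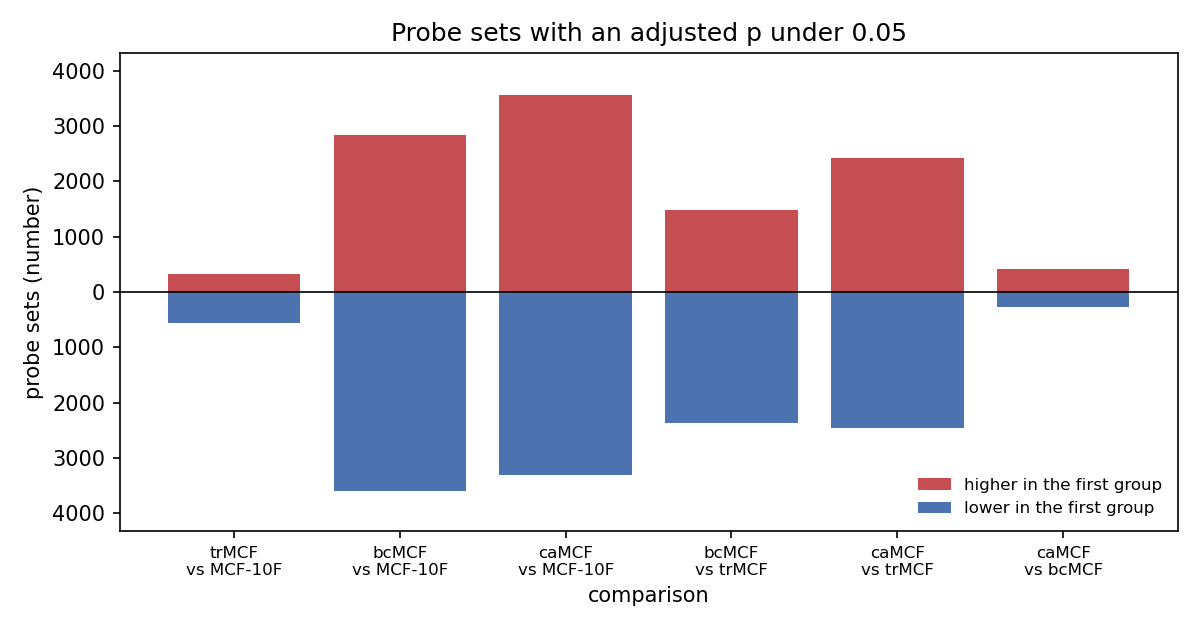
Number of probe sets called by limma at a Benjamini-Hochberg adjusted p under 0.05 in each of 6 comparisons, out of 31699 tested. Bars upward count probe sets higher in the first group and bars downward those lower in it, as 328 and 557 for trMCF against MCF-10F.

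Estrogen receptors and estrogen metabolism were followed because estradiol was the transforming agent. ESR1, the gene of estrogen receptor alpha, measured 37.4 ± 11.3 in MCF-10F, 40.6 ± 1.53 in trMCF, 48.8 ± 19.8 in bcMCF and 42.4 ± 7.77 in caMCF (SD, n = 3), and no comparison called it (adjusted p 0.43 to 0.948). Of its 5 other probe sets 1 was called in bcMCF against MCF-10F and against trMCF. ESR2, the gene of estrogen receptor beta, measured 35.3 ± 1.62, 36.8 ± 14.4, 38.5 ± 8.97 and 32.4 ± 13.9 in the same order (SD, n = 3) and was not called either (adjusted p 0.636 to 0.998). Of 28 estrogen receptor and response genes, 1 rose and 2 fell in trMCF (camera adjusted p = 0.309). MYC, a growth-promoting transcription factor, rose 1.72-fold (adjusted p = 0.034), the cyclin gene CCND1 fell 1.97-fold (adjusted p = 0.00449) and IRS1, an adaptor of insulin signalling, fell 1.30 on the log2 scale (adjusted p = 0.0294). Without the 2 arrays that stood apart 0 genes of this list rose, so MYC was not called, and 3 fell. In caMCF against MCF-10F 3 genes of this list rose and 10 fell (5 and 12 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0598; fry adjusted p = 0.000604). Of 26 estrogen metabolism genes 1 rose and 1 fell in trMCF (camera adjusted p = 0.324). These were AKR1C2, a steroid reductase gene that rose 1.51-fold (adjusted p = 0.0396), and the steroid sulfatase gene STS, which fell 2.11-fold (adjusted p = 0.0195), and neither was called without the 2 arrays that stood apart.

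The comparison of bcMCF with trMCF asks how the invasive clone differed from the transformed cells it came from. CDH1, which encodes the adhesion protein E-cadherin, fell at least 49.5-fold from 548.7 ± 62.5 (SD, n = 3) to the floor (adjusted p = 2.31e-12). ESRP1, an epithelial splicing regulator, fell at least 21.9-fold from 242 ± 15.5 (SD, n = 3) to the floor. CD24, which encodes an epithelial surface glycoprotein, fell 58.0-fold from 1513 ± 421 to 25.5 ± 2.48 (SD, n = 3; adjusted p = 1.74e-10), and the basal keratin KRT15 fell 53.8-fold from 3615 ± 176 to 67.8 ± 10.7 (SD, n = 3; adjusted p = 2.31e-12). FN1 rose 45.8-fold from 62.3 ± 25.5 to 2758 ± 694 (SD, n = 3; adjusted p = 2.39e-05), and SRGN rose 75.5-fold from 12.5 ± 2.36 to 1010 ± 418 (SD, n = 3; adjusted p = 1.71e-11). Both genes were lower in trMCF than in MCF-10F, and the same trMCF arrays enter both comparisons. AXL, a receptor tyrosine kinase of invasive cells, rose 10.8-fold from 23.2 ± 7.57 to 242 ± 13 (SD, n = 3; adjusted p = 1.12e-08). CSF3, which encodes a granulocyte growth factor, rose at least 23.04-fold to 292 ± 160 (SD, n = 3), from the floor. VIM, the mesenchymal filament gene, rose 7.75-fold from 563.5 ± 246 to 4135 ± 684 (SD, n = 3; adjusted p = 2.12e-05). The luminal keratin KRT18 fell 2.20-fold from 1909 ± 168 to 876.5 ± 164 (SD, n = 3; adjusted p = 0.00019), KRT5 fell 1.64-fold (adjusted p = 0.00223), and KRT14 (log2 change 0.44, adjusted p = 0.269) and MKI67 (-0.11, adjusted p = 0.725) were not called.

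The epithelial junction genes fell almost as a whole in bcMCF: of 43 measured, 34 fell, 0 rose and 9 were not called (38 fell adjusted over the list alone), with a median of -2.44 (camera adjusted p = 6.73e-45; adjusted p = 0.000255 with an estimated correlation). EPCAM, an epithelial adhesion gene, fell at least 33.7-fold from 496 ± 38.4 to 14.2 ± 10.5 (SD, n = 3; adjusted p = 5.06e-09), with 1 of 3 bcMCF arrays above the floor. Of 29 basal genes 18 fell and 2 rose (20 and 3 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 2.27e-12; adjusted p = 0.00724 with an estimated correlation). Besides KRT15, S100A8, a calcium-binding protein of inflamed epithelia, fell by 5.20 on the log2 scale (adjusted p = 0.0207), a call that was lost in 7 other settings, among them without any 1 of the trMCF arrays or without bcMCF replicate 2 or 3 (adjusted p 0.0532 to 0.0888). DST, which anchors hemidesmosomes, rose 1.73-fold. Of 26 luminal genes 11 fell and 2 rose, also when adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.000707; adjusted p = 0.0292 with an estimated correlation; adjusted p = 0.0639 on ranks). ALDH1A3, an aldehyde dehydrogenase gene of luminal progenitors, fell 15.6-fold (adjusted p = 0.000179), while the carbonic anhydrase gene CA12 rose 3.98-fold (adjusted p = 6.25e-05).

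Mesenchymal genes moved the other way in bcMCF: of 44 measured 19 rose and 1 fell (23 and 3 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 2.5e-10; adjusted p = 0.0637 with an estimated correlation). FN1 and AXL rose most, and the actin-binding gene TAGLN fell 2.23-fold (adjusted p = 0.031). Of 35 protease and inhibitor genes 8 rose and 1 fell (camera adjusted p = 0.0918). SPOCK1, which encodes a proteoglycan that inhibits proteases, rose 9.13-fold, and the protease inhibitor gene SERPINE2 rose 5.47-fold. Without the 2 arrays that stood apart, 34 junction genes, 15 basal genes and 10 luminal genes fell and 19 mesenchymal genes rose.

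Of 25 p53 target genes 6 fell and 1 rose in bcMCF against trMCF (7 and 1 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.00733; adjusted p = 0.487 with an estimated correlation; fry adjusted p = 0.0719). PERP, a p53 target that also builds desmosomes, fell 3.03-fold (adjusted p = 3.93e-06), and GADD45A, a growth-arrest gene, rose 3.43-fold (adjusted p = 0.0173). The fall of PERP counts in the junction list as well. Without the 2 arrays that stood apart 5 p53 target genes fell and 0 rose, so GADD45A was not called. The call of the p53 list was lost without trMCF replicate 2 (adjusted p = 0.316). Of 55 cell cycle genes 7 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0371; adjusted p = 0.741 with an estimated correlation; fry adjusted p = 0.218). MAD2L1, a gene of the spindle checkpoint, fell 1.77-fold (adjusted p = 0.00102). The cell cycle call was lost without trMCF replicate 2 (adjusted p = 0.0642), without bcMCF replicate 1 (adjusted p = 0.0587) and without bcMCF replicate 2 (adjusted p = 0.067). Of 36 inflammatory genes 4 rose and 3 fell (camera adjusted p = 0.895), with a median of 0.079 and a mean of -0.074. CSF3 and PTX3, which encodes a soluble pattern receptor and rose 12.4-fold, were among the rises, and LCN2, an iron-trapping protein, was among the falls (log2 change -4.37). Of 41 ribosomal protein genes 7 rose and 2 fell, with a median of 0.17 (camera adjusted p = 0.000281; adjusted p = 0.408 with an estimated correlation), and quantile normalization turned that median to -0.036 (adjusted p = 0.262).

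Between bcMCF and trMCF limma called 3850 probe sets, 1476 higher and 2374 lower in bcMCF, of which 1852 differed at least 2-fold. Of the 14410 genes, each read by its representative probe set, 1947 were called. The count of probe sets was 3249 without the 2 arrays that stood apart, 2412 without trMCF replicate 1 and 2297 without trMCF replicate 3.

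The comparison of caMCF with bcMCF asks how the lines grown from tumours of invasive cells differed from the invasive clone, and with all arrays it gave the fewest called probe sets of the 6. With single arrays left out its count ran from 258 to 2110 and that of trMCF against MCF-10F from 236 to 1105, so this rank is not firm. KRT14, which encodes a keratin of basal epithelial cells, fell 38.9-fold from 602.6 ± 251 to 14.6 ± 1.15 (SD, n = 3; adjusted p = 2.99e-09), and its partner KRT5 fell 8.32-fold from 1388 ± 181 to 167 ± 23 (SD, n = 3; adjusted p = 2.93e-09). SFRP1, which encodes a secreted inhibitor of Wnt signalling, rose 13.3-fold from 21.99 ± 8.04 to 280.0 ± 22.3 (SD, n = 3; adjusted p = 2.91e-08). TNC, which encodes the matrix protein tenascin C, rose 4.62-fold from 20.3 ± 5.33 to 92.5 ± 19.8 (SD, n = 3; adjusted p = 0.000419), and LOXL1, of the same enzyme family as LOX, rose 5.65-fold (adjusted p = 0.001). The 1 other probe set of TNC was not called. WASIR2, a non-coding transcript at the floor in all 3 bcMCF arrays, rose at least 19.7-fold to 218 ± 9.26 (SD, n = 3; adjusted p = 1.4e-08). MUC1, which encodes a luminal mucin, fell 4.46-fold (adjusted p = 0.00653). C3, which encodes a complement protein, fell 5.70-fold (adjusted p = 0.0137), and that call was lost in 4 other settings, among them without bcMCF replicate 3 (adjusted p = 0.0651) and without caMCF replicate 1 (adjusted p = 0.0502). VIM (log2 change 0.12, adjusted p = 0.86), FN1 (-0.38, adjusted p = 0.692), KRT18 (0.037, adjusted p = 0.927) and MKI67 (0.077, adjusted p = 0.846) were not called, and CDH1 lay at the floor in both groups.

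Of 36 inflammatory genes 4 fell and 0 rose in caMCF (8 and 0 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 2.35e-06; adjusted p = 0.35 with an estimated correlation; fry adjusted p = 0.101). TNFAIP6, which encodes a hyaluronan-binding protein, fell 3.08-fold (adjusted p = 0.00219). Of 43 junction genes 4 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.00185; adjusted p = 0.183 with an estimated correlation). The desmosomal genes PKP2 and DSG2 fell 2.64-fold and 2.46-fold, while the tight-junction genes CLDN4 and LSR rose 3.85-fold (adjusted p = 0.000928) and 3.38-fold. Of 29 basal genes 4 fell and 1 rose, also when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.016; adjusted p = 0.242 with an estimated correlation). The 2 largest falls were those of KRT14 and KRT5, and the gap-junction gene GJB2 rose 3.40-fold (adjusted p = 4.89e-05). The basal call was lost without bcMCF replicate 2 (adjusted p = 0.11), without caMCF replicate 3 (adjusted p = 0.0538), with quantile normalization (adjusted p = 0.0733), without a filter (adjusted p = 0.0678) and on ranks (adjusted p = 0.144). Of 44 mesenchymal genes 2 rose and 4 fell (camera adjusted p = 0.318). SPARC, which encodes a collagen-binding matrix protein, rose at least 28.3-fold from 8.84 ± 3.38, where 1 of 3 arrays lay above the floor, to 329 ± 48.1 (SD, n = 3; adjusted p = 2.99e-09), while DCN fell 4.23-fold (adjusted p = 0.000337). Without the 2 arrays that stood apart 3 mesenchymal genes rose and 2 fell.

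Of 26 estrogen metabolism genes 4 fell and 0 rose in caMCF against bcMCF, with a median of -0.15 (camera adjusted p = 0.00733; adjusted p = 0.259 with an estimated correlation). AKR1C1, a steroid reductase gene, fell 2.88-fold (adjusted p = 0.000136), and the estrogen sulfotransferase gene SULT1E1 fell by 2.47 on the log2 scale (adjusted p = 0.0293). The SULT1E1 call was lost in 8 other settings, among them without bcMCF replicate 3 or any 1 of the caMCF arrays (adjusted p 0.0715 to 0.118). The call of the list was lost without bcMCF replicate 1 (adjusted p = 0.0782) and on ranks (adjusted p = 0.0606), and 2 of its genes fell without the 2 arrays that stood apart. Of 28 estrogen receptor and response genes 2 fell and 0 rose (5 and 1 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0491; adjusted p = 0.177 with an estimated correlation). The estrogen-response call was lost in most other settings (adjusted p 0.0523 to 0.177), among them without bcMCF replicate 2 or 3 and without caMCF replicate 1 or 2 (adjusted p 0.0665, 0.109, 0.0576 and 0.088). The chemokine gene CXCL12 fell 2.22-fold and MYC fell 1.94-fold. Without the 2 arrays that stood apart 1 estrogen-response gene fell and 0 rose. Of 41 ribosomal protein genes 1 fell, RPS6 (1.73-fold, adjusted p = 5.89e-05), with a median of -0.064 (camera adjusted p = 0.0135; adjusted p = 0.581 with an estimated correlation), which quantile normalization turned to 0.034 (adjusted p = 0.762). The ribosomal call was also lost without bcMCF replicate 3 (adjusted p = 0.154) and without caMCF replicate 3 (adjusted p = 0.0551). Of 55 cell cycle genes limma called 0, and at an unadjusted p under 0.05 8 were higher and 0 lower (camera adjusted p = 0.263; quantile normalization adjusted p = 0.0115). Of 35 protease genes 3 rose and 1 fell (camera adjusted p = 0.77), with a median of -0.12 and a mean of 0.18. TIMP3 rose 4.34-fold.

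Between caMCF and bcMCF limma called 689 probe sets, 416 higher and 273 lower in caMCF, of which 424 differed at least 2-fold. Of the 14410 genes, each read by its representative probe set, 358 were called. The count of probe sets was 482 without the 2 arrays that stood apart, 238 higher and 244 lower, so the excess of higher probe sets was not stable. It was 2110 without bcMCF replicate 2, 258 without caMCF replicate 1, 268 without caMCF replicate 2 and 322 without caMCF replicate 3.

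The comparison of caMCF with MCF-10F spans the whole course from parental to tumour-derived cells. CDH1 fell at least 67.4-fold from 745 ± 70.0 (SD, n = 3) to the floor (adjusted p = 3.66e-13), and DSP, which encodes the desmosomal protein desmoplakin, fell at least 76.5-fold from 845 ± 53.3 (SD, n = 3; adjusted p = 0.000161). CD24 fell 95.1-fold from 2423 ± 401 to 26.6 ± 10.5 (SD, n = 3), KRT15 fell 91.7-fold from 3792 ± 245 to 42.2 ± 10.4 (SD, n = 3; adjusted p = 3.26e-13) and KRT14 fell 47.0-fold from 692 ± 127 to 14.6 ± 1.15 (SD, n = 3; adjusted p = 1.81e-10). The matrix genes COL6A3, from 18.1 ± 4.75 to 361 ± 69.2 (SD, n = 3), and SPARC, from the floor to 329 ± 48.1 (SD, n = 3), rose 20.2-fold (adjusted p = 8.01e-09) and at least 29.6-fold (adjusted p = 2.13e-10). AXL rose 17.7-fold from 16.5 ± 1.04 to 293 ± 18.4 (SD, n = 3; adjusted p = 6.54e-10), and APOBEC3B, which encodes a DNA-editing enzyme, rose 15.3-fold from 15.3 ± 2.09 to 233 ± 21.5 (SD, n = 3; adjusted p = 5.47e-08). VIM rose 9.24-fold from 495 ± 157 to 4441 ± 200 (SD, n = 3; adjusted p = 5.57e-06), and MKI67 rose 1.83-fold (adjusted p = 0.00153). The 1 other probe set of VIM was not called, and of the 3 others of MKI67 1 was called higher. KRT5 fell 15.5-fold from 2590 ± 400 (SD, n = 3; adjusted p = 8.6e-12) and KRT18 fell 1.70-fold (adjusted p = 0.00268). FN1 was not called (log2 change 1.08, adjusted p = 0.121).

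Of 43 junction genes 40 fell and 0 rose in caMCF against MCF-10F, also when adjusted over the list alone, with a median of -2.62 (camera adjusted p = 4.81e-45; adjusted p = 0.000255 with an estimated correlation). Of 29 basal genes 22 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -2.10 (camera adjusted p = 2.74e-19; adjusted p = 0.00237 with an estimated correlation). Of 26 luminal genes 11 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.11 and a mean of -1.03 (camera adjusted p = 0.000459; adjusted p = 0.0262 with an estimated correlation; adjusted p = 0.106 on ranks). AGR2, a secretory-pathway gene of luminal cells, fell 21.3-fold, and the simple-epithelial keratin KRT19 rose 2.72-fold (adjusted p = 0.0083). Of 44 mesenchymal genes 16 rose and 6 fell (16 and 7 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.0213; adjusted p = 0.481 with an estimated correlation). TGFB2, which encodes a transforming growth factor, fell 9.25-fold (adjusted p = 0.000221), and IGFBP3, which binds insulin-like growth factors, fell 6.64-fold (adjusted p = 0.01). The mesenchymal call was lost without MCF-10F replicate 1 (adjusted p = 0.0617), without MCF-10F replicate 3 (adjusted p = 0.0532), without the 2 arrays that stood apart (adjusted p = 0.0961), without a filter (adjusted p = 0.0647) and on ranks (adjusted p = 0.177). Without the 2 arrays that stood apart 20 basal genes fell and 13 mesenchymal genes rose.

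Of 55 cell cycle genes 33 rose and 0 fell in caMCF against MCF-10F (41 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 3.38e-11; adjusted p = 0.196 with an estimated correlation). The spindle-checkpoint gene BUB1 rose 2.54-fold (adjusted p = 0.000454) and the phosphatase gene CDC25C rose 2.47-fold. Of 25 p53 target genes 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 9.84e-06; adjusted p = 0.242 with an estimated correlation). GDF15 fell 10.3-fold (adjusted p = 1.12e-05) and TP53I3 fell 7.46-fold. Of 36 inflammatory genes 12 fell and 4 rose (13 and 4 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 0.00218; adjusted p = 0.581 with an estimated correlation; fry adjusted p = 0.0907). LCN2 fell 39.0-fold and PTX3 rose at least 26.9-fold. The inflammatory call was lost without MCF-10F replicate 2 (adjusted p = 0.0531), and 5 inflammatory genes fell without the 2 arrays that stood apart. Of 41 ribosomal protein genes 17 rose and 4 fell (22 and 4 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.00237; adjusted p = 0.487 with an estimated correlation). Quantile normalization lowered the ribosomal median to 0.071 (adjusted p = 0.709), the mean of all probe sets of a gene also ended the call (adjusted p = 0.197), and 13 rose and 2 fell without the 2 arrays that stood apart.

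**Figure D3:**
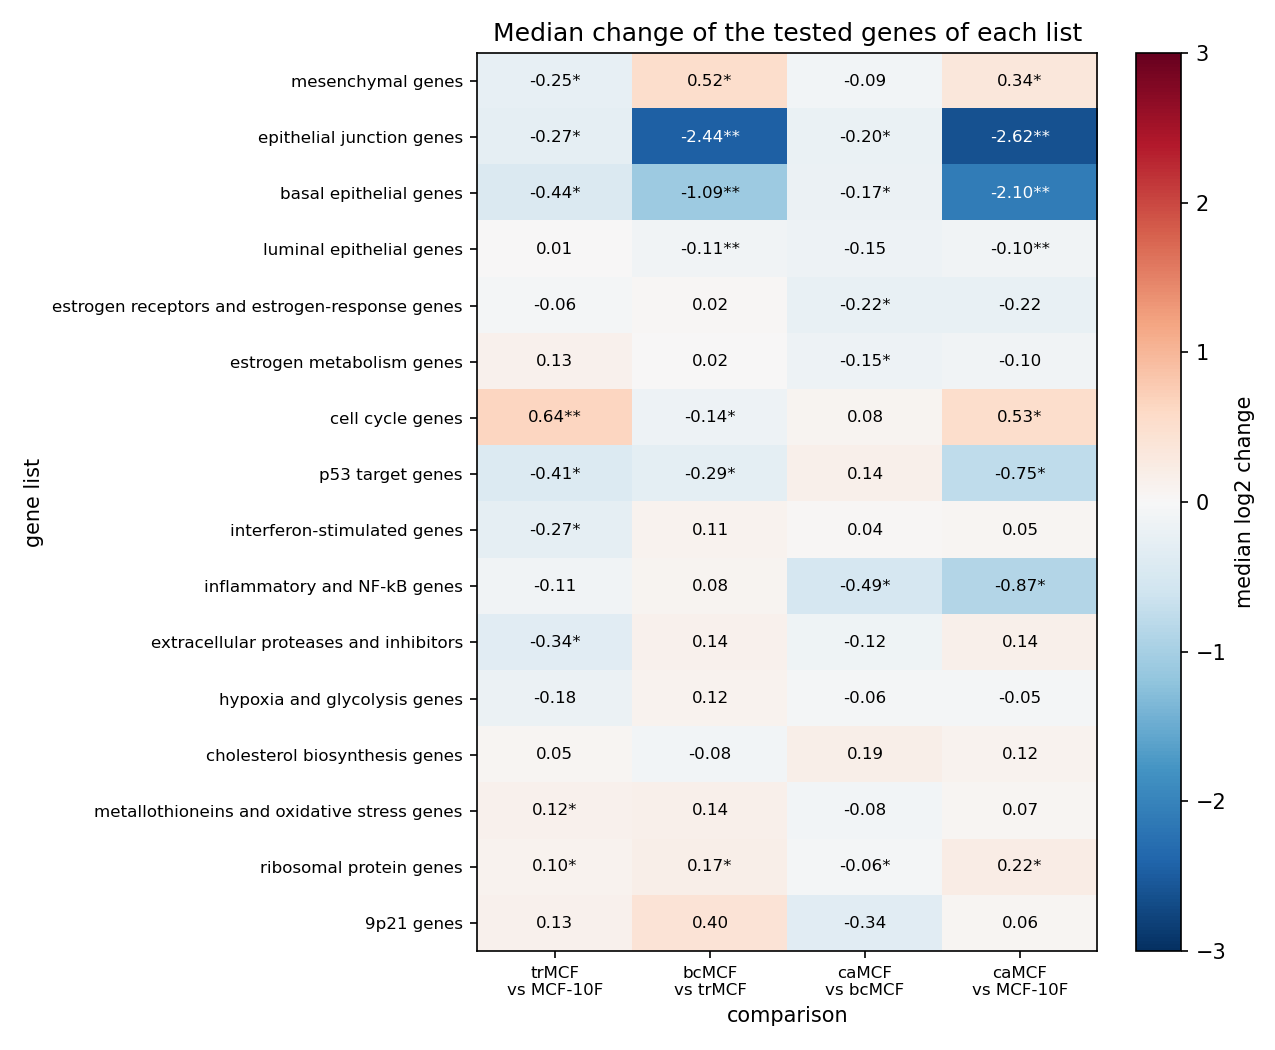
Median log2 change of the members of 16 gene lists (vertical) in 4 comparisons (horizontal), shown as colour and number. One star marks a camera adjusted p under 0.05 at the preset correlation and 2 stars mark lists called with an estimated correlation as well. The epithelial junction list had the lowest median, -2.62 in caMCF against MCF-10F.

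Between caMCF and MCF-10F limma called 6862 probe sets, 3566 higher and 3296 lower in caMCF, of which 3091 differed at least 2-fold. Of the 14410 genes, each read by its representative probe set, 3410 were called. The count of probe sets was 6510 without the 2 arrays that stood apart. The direct comparison of bcMCF with MCF-10F called 6445 probe sets, 2845 higher and 3600 lower, and 4079 without those arrays. FN1 rose 2.75-fold in bcMCF against MCF-10F (adjusted p = 0.0437), a call that was lost in 9 other settings. Of the probe sets higher in bcMCF, 1865 were also higher in caMCF, against 320 for independent sets, and 2358 were lower in both, against 374, while 9 moved in opposite directions. The 2 comparisons share the MCF-10F arrays, which were too few to divide between them, so part of this excess may come from the shared controls: 20 simulated data sets without any difference gave a correlation of changes of 0.50, against 0.82 observed, a covariance of 0.0361, against 0.411, and at most 0 probe sets called by limma in both. These simulations held no true changes, so they cannot show how many shared calls the common arrays add where many probe sets differ. The comparison of caMCF with trMCF called 4871 probe sets, 2415 higher and 2456 lower in caMCF. It was 6341 without the 2 arrays that stood apart, 3183 without caMCF replicate 1 and 3181 without caMCF replicate 2. Of the 43 junction genes 40 fell and 0 rose there (camera adjusted p = 2.42e-49; adjusted p = 0.000255 with an estimated correlation).

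The remaining lists were not called between caMCF and MCF-10F. Of 33 hypoxia and glycolysis genes 4 rose and 7 fell (camera adjusted p = 0.424), or 2 and 9 without the 2 arrays that stood apart. The glucose transporter SLC2A3 rose 9.38-fold. Of 18 cholesterol biosynthesis genes 3 rose and 3 fell (camera adjusted p = 0.799). Of 3 genes of 9p21, which holds the tumour suppressor CDKN2A, limma called 0, also at an unadjusted p under 0.05 (camera adjusted p = 0.973). Genes of other cell types were followed because tumour lines can carry other cells. The tumours grew in mice, so cells of the host would be mouse cells. How well these human probe sets measure mouse transcripts was not tested, so the lists cannot decide whether such cells were present. Of 14 fibroblast genes 1 rose and 2 fell (camera adjusted p = 0.821), but 8 of the 14 stand in other lists and 11 passed the filter in MCF-10F itself. Of 13 leukocyte genes, 8 of them above the filter in MCF-10F, 1 rose and 2 fell (camera adjusted p = 0.81), the rise being that of LAPTM5, a lysosomal protein. Of 10 endothelial genes, 8 above the filter in MCF-10F, 2 rose and 0 fell (camera adjusted p = 0.516). Of 7 adipocyte genes, 5 above the filter in MCF-10F, 1 fell (camera adjusted p = 0.77). Between caMCF and bcMCF 1 of the 14 fibroblast genes fell, DCN (camera adjusted p = 0.000707; adjusted p = 0.205 with an estimated correlation), and between bcMCF and trMCF 2 rose (camera adjusted p = 0.0371; adjusted p = 0.432 with an estimated correlation), a call that was lost without trMCF replicate 3 (adjusted p = 0.139), without bcMCF replicate 3 (adjusted p = 0.156) and on ranks (adjusted p = 0.0902).

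Chromosomes were tested as sets because the study also took DNA for copy-number arrays. Of 518 genes tested on chromosome 4, 183 fell and 11 rose in caMCF against MCF-10F, with a median log2 change of -0.39 where the median of all genes was 0.050 (camera adjusted p = 1.86e-10; adjusted p = 0.275 with an estimated correlation). In bcMCF against MCF-10F 205 fell and 19 rose, with a median of -0.40 (camera adjusted p = 2.86e-09; adjusted p = 0.318 with an estimated correlation). In bcMCF against trMCF the median was -0.38 (camera adjusted p = 4.97e-10; adjusted p = 0.286 with an estimated correlation), so the genes of this chromosome were lower than in either earlier group. Without a filter the 3 medians shrank to -0.096, -0.022 and -0.034 in the same order. Of 214 genes on chromosome 18, 16 fell and 1 rose in caMCF against bcMCF, with a median of -0.18 (camera adjusted p = 1.78e-05; adjusted p = 0.182 with an estimated correlation). Of 655 genes on chromosome 5, 163 rose and 49 fell in caMCF against MCF-10F, with a median of 0.22 (camera adjusted p = 0.00322; adjusted p = 0.272 with an estimated correlation). In trMCF against MCF-10F, genes of chromosome 11 (3 rose and 44 fell, median -0.096, camera adjusted p = 0.00119) and chromosome 15 (1 rose and 18 fell, median -0.15, camera adjusted p = 0.000322) were lower, each with an adjusted p = 0.182 with an estimated correlation. Without a filter these 2 medians were -0.057 and -0.077. Neither chromosome was called in bcMCF (medians 0.076 and 0.027) or caMCF (0.039 and -0.025) against MCF-10F (camera adjusted p 0.445 to 0.992). Genes of chromosome 11 were higher in bcMCF than in trMCF (median 0.17, camera adjusted p = 0.037). Chromosome 1 was higher and chromosome 8 lower than in trMCF in both bcMCF (camera adjusted p = 0.0119 and 0.0279) and caMCF (0.00653 and 0.0116). Most chromosome calls in bcMCF against trMCF were lost without a filter. With the correlation estimated, camera called 0 chromosomes in any comparison, where 1 to 5 per comparison had an unadjusted p under 0.05, and fry called 1 to 6.

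**Figure D4:**
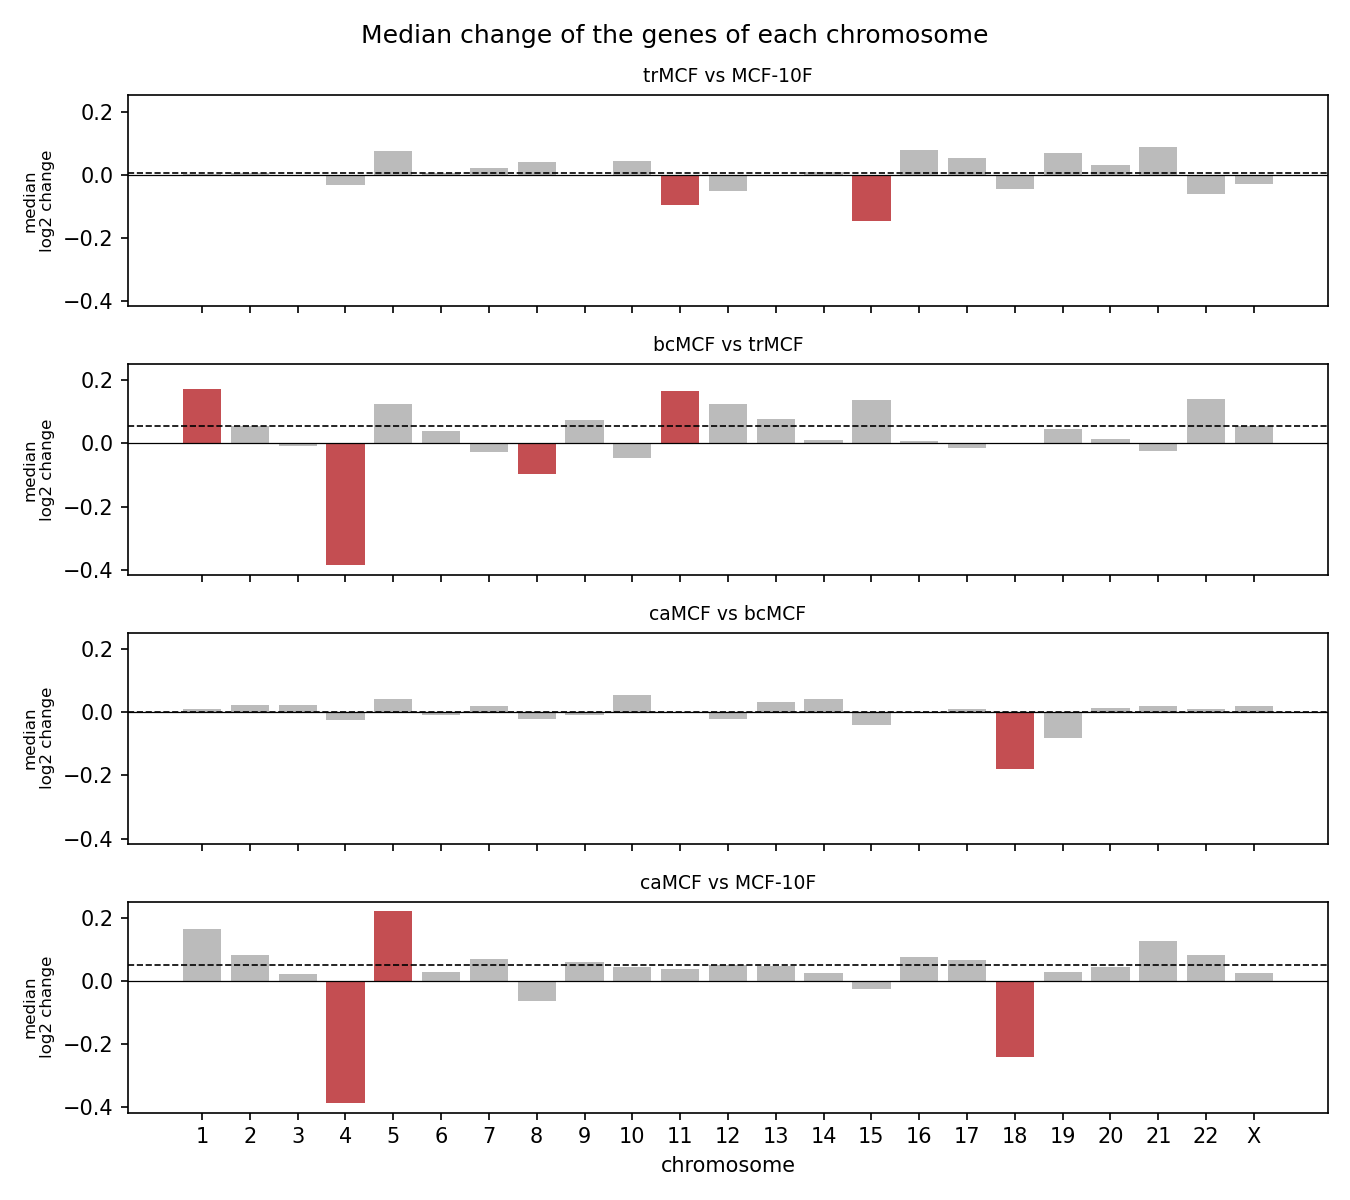
Median log2 change of the genes on each of chromosomes 1 to 22 and X (horizontal) in 4 comparisons. Red bars mark chromosomes with a camera adjusted p under 0.05 at the preset correlation, and the dashed line is the median of all genes. Chromosome 4 stood at -0.39 in caMCF against MCF-10F.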

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

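The settings with array quality weights and with both arrays that stood apart left out were chosen only after the results had been seen. Where a count moved, the cause was not tested. Background and detection values were not given in the sources used here, so how far signal over background limits the calls of dim probe sets was not tested. Without a filter limma called 445 probe sets in trMCF against MCF-10F and 425 in caMCF against bcMCF, camera called 1 chromosome in bcMCF against MCF-10F and 1 in bcMCF against trMCF, and the mean correlations between MCF-10F and trMCF, bcMCF and caMCF were 0.955, 0.898 and 0.904, with 0.915 and 0.918 between trMCF and the later 2 groups. Without trend and robust fitting 508 were called in trMCF against MCF-10F. With only the 2 groups compared, the counts were 1442 (trMCF against MCF-10F), 3570 (bcMCF against MCF-10F), 1988 (bcMCF against trMCF), 7724 (caMCF against trMCF) and 249 (caMCF against bcMCF). A treat test against a 1.5-fold change called 74, 1169, 1564, 681, 1053 and 65 in trMCF, bcMCF and caMCF against MCF-10F, bcMCF and caMCF against trMCF, and caMCF against bcMCF. With an estimated inter-gene correlation camera called 1, 2, 3, 3, 3 and 0 lists in the same order and 0 chromosomes in each, where 6, 5, 5, 4, 4 and 4 lists had an unadjusted p under 0.05 and fry called 8, 10, 9, 9, 8 and 7. Camera on ranks called 4 lists in caMCF against bcMCF. Array weights, lowest for bcMCF replicate 3 (0.276), gave 3129 in trMCF against MCF-10F and 9225 in caMCF against trMCF. The weights of bcMCF replicate 1 (0.497) and trMCF replicate 2 (0.598) were below that of MCF-10F replicate 3 (0.721). Without both arrays that stood apart the counts were 489 in trMCF and 4079 in bcMCF against MCF-10F, with 5 chromosomes in trMCF against MCF-10F and 2 in caMCF against bcMCF.

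Leaving out single arrays gave 236 to 1105 probe sets in trMCF against MCF-10F, 2297 to 5092 in bcMCF against trMCF, 3181 to 3583 in caMCF against trMCF and 258 to 2110 in caMCF against bcMCF. It gave 1 to 2 chromosomes in bcMCF against MCF-10F, 2 to 5 in bcMCF against trMCF and 1 to 2 in caMCF against bcMCF. Quantile normalization reversed the ribosomal protein genes in bcMCF against trMCF (-0.036) and caMCF against bcMCF (0.034). With the replicate number as a replicate block limma called 704, 5990, 6497, 3622, 4526 and 611 probe sets in the order above. Of 18 pairs of arrays with the same number, 3 correlated above 0.1 after the group means were removed (range -0.246 to 0.288), and 3 of 12 arrays correlated best with their own number, so the numbers gave no sign of paired samples.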

Other observations

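The tests of ERK pathway genes, the test of single aberrant HRAS arrays, the test of a few strongly changed genes and the blocks of chromosome 18 were chosen only after the results had been seen, and so were HRAS and the genes named with it.

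Of 29 metallothionein and oxidative stress genes 9 rose and 3 fell in bcMCF against trMCF (camera adjusted p = 0.165; fry adjusted p = 0.00225), and 5 rose and 2 fell without the 2 arrays that stood apart. MT1X, which encodes a metal-binding metallothionein, rose 2.70-fold from 2008 ± 704 to 5198 ± 418 (SD, n = 3; adjusted p = 0.00651), and FTL, the light chain of ferritin, rose 3.15-fold (adjusted p = 1.3e-06). In caMCF against MCF-10F FTL rose 5.08-fold (adjusted p = 1.46e-08), and 11 of the 29 rose and 5 fell (camera adjusted p = 0.309; fry adjusted p = 0.000717). NQO1, a quinone reductase that also acts on estrogen quinones, rose by 0.82 on the log2 scale in bcMCF against trMCF. Of 33 hypoxia and glycolysis genes 5 rose and 5 fell in that comparison (camera adjusted p = 0.709), among them SLC2A3 (3.79-fold higher) and STC1, a secreted hormone gene (log2 change -1.37).

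The genes of chromosome 4 were lower in bcMCF and caMCF. A larger shift of dim genes than of bright ones is argued against by 10000 random gene sets matched on signal, whose lowest median was -0.022 in caMCF against MCF-10F, where chromosome 4 lay at -0.39. A few strongly changed genes are argued against by the share of its genes below the median of all genes, 70.5% in bcMCF and 74.5% in caMCF. A high share follows in part from the low median of the chromosome, so it is not separate support for the shift. Of its 20 blocks of at least 25 neighbouring genes, 90% (18) in caMCF and 17 in bcMCF against MCF-10F lay below the 5th percentile of random blocks, so the shift was not that of a single stretch. The lower expression may follow from loss of a copy of this chromosome, which was not tested here. With an estimated correlation camera did not call the set in caMCF against MCF-10F (adjusted p = 0.275, range over all settings 1.73e-11 to 0.275). Nor did it in bcMCF against MCF-10F (adjusted p = 0.318). Without a filter the medians of the chromosome shrank strongly in both, as given above.

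The genes of chromosome 18 were lower in caMCF than in bcMCF. The lowest of 10000 random sets matched on signal had a median of -0.108, against -0.18 for the chromosome, which argues against a shift of dim genes. Of its 8 blocks the first 3, from USP14 to IMPACT, had medians of 0.012, 0.050 and 0.074, and the last 5, from SS18 to PARD6G, had medians of -0.43, -0.33, -0.22, -0.20 and -0.21. A loss confined to the later part of the chromosome might give this picture and was not tested, and the chromosome was not called with an estimated correlation.

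HRAS, which encodes a small GTPase upstream of ERK, rose 7.73-fold in bcMCF against trMCF from 164 ± 6.73 to 1277 ± 167 (SD, n = 3; adjusted p = 1.74e-10) by its 1 probe set, and was not called in trMCF against MCF-10F (adjusted p = 0.775). The lowest of the 6 bcMCF and caMCF arrays read 1087 and the highest of the others 198, so no single array made the difference. The 20 nearest genes had a median change of -0.0995 in caMCF against MCF-10F (95% bootstrap interval -0.314 to 0.153), far below 1.52, the HRAS change halved, which argues against a gain of the surrounding stretch. Of 15 output genes of the ERK pathway, 2 others seen to be raised before the list was written being left out, 10 rose and 1 fell in caMCF against trMCF (camera p = 7.14e-06, adjusted p = 2.86e-05 over 4 comparisons, or 9.96e-05 also without CCND1, which had fallen in trMCF; adjusted p = 0.0616 with an estimated correlation), with a log2 change of 1.91 for FOSL1 and of -1.29 for DUSP4, and over the 4 comparisons the adjusted p ran up to 0.0445, or 0.207 with the estimated correlation. More signalling through the ERK pathway may go with the higher HRAS signal, but an introduced copy of HRAS or another line of origin was not tested.

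The 6 arrays of 2 groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 split, the real one, gave the most probe sets. It gave 885, 6445 and 6862 in trMCF, bcMCF and caMCF against MCF-10F, 3850 and 4871 in bcMCF and caMCF against trMCF and 689 in caMCF against bcMCF. The highest other split gave 3 in bcMCF against trMCF and 0 in the other 5 by limma. Each other split mixed the 2 groups, so their difference entered the spread within groups and lowered these counts. The counts therefore do not show what chance alone would give. At an unadjusted p under 0.05 those other splits gave at most 1957, 3629, 1517, 4900, 1014 and 3971 in that order, and the real ones 4950, 10598, 10460, 8161, 8652 and 5674.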
